A study of Mus musculus with 8 samples.

How the data were processed

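Acetylation of lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in mouse embryonic stem cells of the E14tg2a line. Per the labels, the cells stably expressed cRAF-ErT2, a RAF kinase fused to an oestrogen receptor domain, which activates the MAP kinase ERK when 4-hydroxytamoxifen (4OHT) is added. They were grown in serum with LIF and 2 uM Chir99021, a GSK3 inhibitor that activates WNT signalling. The medium was changed 24 h before treatment to one for which the labels name serum, LIF and 250 nM PD173074, an inhibitor of FGF receptors. Cells were then left untreated or given 250 nM 4OHT for 2 h. The labels give clones a and b in each treatment, so 2 untreated and 2 treated H3K27ac libraries were compared. The 4 input libraries were not analysed here.

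Per the submitters' processing notes, reads were handled with Bowtie2, bedtools and MACS2 on the mm10 mouse genome build. Versions, thresholds and the use of the inputs in calling are not given in the sources used here. Each deposited file lists the peaks of a single library, so peaks were called per library. The score of each peak is the authors' own value, deposited with the peak and with no stated scale; it was used only to rank or filter peaks within its own list. The files give no read counts, so the depth is unknown, and a region called in one list and not in another may lie just above a threshold in the first and just below it in the second.

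Peaks of the 4 lists that overlapped by 1 bp or more were merged into union regions, and a region was called in a library if a peak of that library overlapped it. Regions called in both treated libraries and in neither untreated library are termed gained, and the opposite pattern lost. Regions were assigned to the nearest of 21887 protein-coding genes within 100 kb, using a RefSeq gene table of assembly GRCm38.p6, whose coordinates are those of mm10. The table gives gene intervals without strand, so transcription start sites could not be placed. This is a departure from the design, which named start sites: distance was taken to the gene interval, nearness to a promoter was replaced by lying within 1 kb of either end of a protein-coding gene, and windows were drawn around gene intervals. The deposited lists hold no q-value, so the stricter alternative took the upper 50% of each list by score. No genome sequence was used here, so base composition and motifs were not examined.

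For each gene, the length covered by peaks within the gene and 50 kb on either side was summed per library. Genes with a mean of at least 1000 bp over the 4 libraries were compared with limma, with a mean-dependent prior variance, on log2(covered bp + 500), with Benjamini-Hochberg adjustment at 0.05 and no clone term. Log2 changes are on that scale, which understates changes of short lengths. Windows of neighbouring genes share peaks, so their tests are not independent. Covered length also depends on how much was called in a library. Lists of genes were tested on loci with camera, with a preset correlation of 0.01 and with an estimated correlation, and with fry. Gained against lost regions of a list were compared with those of all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 13 lists. Regions and genes are not independent replicates, so these p-values describe the regions of these libraries.

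The clone letters in the labels pair the treatments. As a check, the deviations of clone a from its group's mean correlated at 0.611 over loci between untreated and treated cells. A fit with clone as a factor was therefore run as an alternative. With 2 clones per treatment, p-values of the fit without a clone term measure the spread between these clones. Clone as a factor removes that spread. Its p-values then rest on how far the treatment change differs between the clones, and on variance borrowed across loci. The borrowed degrees of freedom (6.64) outnumber those of each locus, and loci share windows.

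The design, the 13 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took 11 genes always (Egr1, Fos, Dusp6, Spry4, Nanog, Klf4, Esrrb, Pou5f1, Gata6, Fgf5 and Actb), up to 4 members per list with gained and up to 4 with lost regions, the nearest genes of the 10 gained and 10 lost regions ranked highest by score, and the 5 loci with the largest increase and the 5 with the largest decrease past the threshold. A locus that this rule names is not reported here. Members of the lists whose loci passed the threshold are also named; they were chosen after their values were seen. Alternatives covered the score filter, equal list lengths, the top 20000 peaks, 50% coverage of a region, merging within 1000 bp, assignment within 20 kb, windows of 10 and 100 kb, pseudocounts of 100 and 2000 bp, no filter on length, scaling to each library's covered length, clone as a factor, and leaving out each library in turn.

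Region handling was checked on simulated peaks, where 200 of 200 planted gained and 200 of 200 planted lost regions were found. The locus fit was tested on simulated data for the same 16049 loci, with 100 loci changed by 1 and 100 by 2 on the log2 scale, under noise models that differ in what clones share. A first simulation with noise independent in each library recovered 1% and 39% of these sizes without a clone term, and 0% of either with it. A second simulation, made after the first had been seen and with part of the noise shared by a clone's libraries, recovered 6% and 69% without a clone term, with 0 false calls. With clone as a factor it recovered 78% and 98%, and 8.33% of its calls were false, above the nominal level. How sensitive the fits are thus depends on the noise assumed. The correlation of 0.611 between a clone's deviations argues against noise independent in each library. In the second simulation 0.669% of unchanged loci had an unadjusted limma p under 0.05 without a clone term. The main fit was thus conservative under that noise, and a locus it did not call may still have changed.

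Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, R 4.3.3 with limma 3.58.1, and bedtools 2.31.1.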

Results

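H3K27ac peak lists were compared between untreated embryonic stem cells and cells given 4OHT for 2 h to activate ERK. Clones a and b were used in each group. Activation of ERK was not measured in these data. The labels name only untreated and 4OHT-treated cells, with no vehicle control. Effects of 4OHT itself can therefore not be told apart from those of ERK. The untreated lists held 61203 peaks in clone a, covering 53.1 Mb, and 63276 in clone b, covering 50.4 Mb. The treated lists held 59170 peaks (51.5 Mb) in clone a and 62764 (50.7 Mb) in clone b. Median peak widths were 531 and 503 bp in untreated clones a and b, and 539 and 511 bp in the treated ones. Read depth is unknown, so a missing peak is not evidence that the mark was absent.

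The first question was where H3K27ac peaks appeared or disappeared after 4OHT. Regions gained in both clones lay around Spry4, Etv4 and Spry2, which are feedback regulators or ETS factors of the FGF and ERK pathway, around Phlda1 and Myc, and within Manba. Regions lost in both clones lay near Sox1, Prdm14, Socs3 and Lefty1. Across the genome 5130 regions were gained and 5185 lost, out of 82792 union regions, of which 30131 were called in all 4 libraries.

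Regions that changed in both clones mostly changed the same way. Within clone a 13289 regions were gained and 14912 lost, and within clone b 15582 were gained and 14839 lost. Of these, 5130 were gained and 5185 lost in both clones, so most changes in either clone were not changes in the other. Of regions that changed in both, 92.3% changed the same way, with an odds ratio of 142 (95% interval 123 to 164; Fisher's exact test, two-sided, over regions). Regions among the top 20000 of one list and absent from the whole other list of that clone were fewer: 174 were gained and 104 lost in both clones, and 0 changed in opposite directions. The other ways to pair the libraries gave 5220 regions that separated the clones and 866 in the crossed pairing, against 10315 for treatment. Only 3 pairings exist, so no test of them can reach 0.05. Jaccard indices over covered bases were 0.644 ± 0.000518 (SD, n = 2 pairs) for the same treatment, 0.586 ± 0.0157 for the same clone and 0.535 ± 0.0318 for pairs that differed in both.

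**Figure D1:**
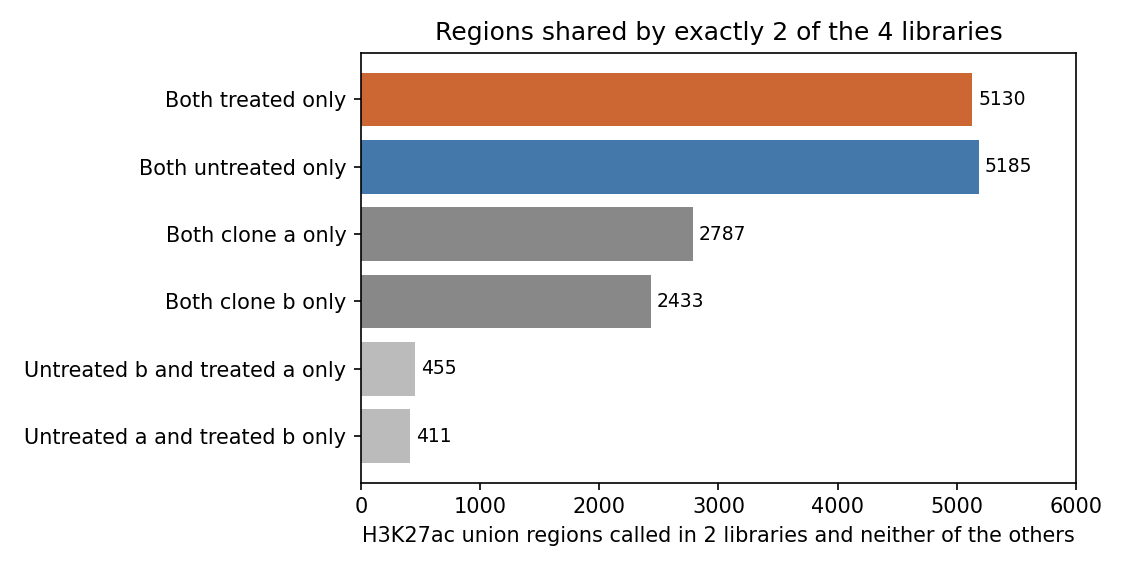
Bars give the number of union regions called in exactly 2 of the 4 libraries, for each pair of libraries. The 5130 gained and 5185 lost regions outnumber the 2787 and 2433 that separate the clones and the 455 and 411 of the crossed pairs.

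The gained regions with the highest within-list score ranks were at Dnah1 (chromosome 14, 31324136 to 31325697, mm10), 84.4 kb from Tfap2c, at Snai3, within Cubn, and 23.6 kb from Ap1s3. Further ones lay within Efr3b, Sema5b and Pitpnc1, 13.1 kb from Rasl11a and 222 kb from Sox4. The lost regions ranked highest were 19.2 kb from Cdk18 (chromosome 1, 132158936 to 132160520), within Smg9, Pax5, Foxn3, Oc90 and Zfp607b, 65.5 kb from Orc5 and 19.03 kb from Gpc3. Another 2 lay over 100 kb from any protein-coding gene, the nearest being Cdh8 and 1700012A03Rik. Both classes were weak within their lists: the median score percentile was 35.2 and 38.5 for gained regions in treated clones a and b, and 34.8 and 32.1 for lost regions in untreated clones a and b, against 72.0 to 73.1 for regions called in all 4 libraries.

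Gained regions lay at gene ends more often than lost ones. Of gained regions 16.1% (828) lay within 1 kb of an end of a protein-coding gene, as did 6.50% (337) of lost regions and 37.9% of regions called in all 4 libraries. The odds ratio of gained against lost was 2.77 (95% interval 2.42 to 3.17, Fisher's exact p = 3.29e-55, over regions). It was 5.55 among the top 20000 peaks of each list and 4.28 in the upper 50% by score, and 1.74 without treated clone a. In both score settings regions were called anew from the shortened lists. A region gained there may still hold a weaker peak in an untreated list, and a lost one in a treated list. The top 20000 gave 1859 gained regions, whereas 174 were absent from the whole untreated lists. Over the whole lists, overlap with a gene was 57.1% for gained and 41.9% for lost regions.

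The second question was whether genes of known ERK programmes differed from other genes. Immediate-early genes, which are transcribed within minutes of ERK signalling, held 34 gained and 11 lost regions (75.6% gained, against 51.3% at other genes; odds ratio 2.93, 95% interval 1.45 to 6.42, adjusted Fisher's exact p = 0.00915). Phlda1 held 9 gained and 0 lost regions, Myc 7 and 2, Klf6 4 and 1, and Arc 3 and 0, whereas Atf3 held 0 and 3 and Btg2 0 and 2. The Phlda1 regions lay 31.1 to 80.8 kb from the gene, and the lost Myc regions 99.2 and 99.98 kb from it. Feedback regulators and ETS factors held 28 gained and 7 lost regions (80.0% gained; odds ratio 3.79, 95% interval 1.62 to 10.3, adjusted Fisher's exact p = 0.00765). Spry4 held 6 gained and 0 lost regions, Etv4 4 and 0, and Spry2 3 and 0. Epha2 held 2 of each, Spred2 1 of each, Spry1 1 and 2, and Etv5 0 and 1. Without Phlda1 the immediate-early odds ratio was 2.15 (95% interval 1.02 to 4.86, adjusted Fisher's exact p = 0.109), and without Spry4 that of feedback genes was 2.98 (1.23 to 8.26, 0.0963). With each gene counted once they were 2.76 (0.953 to 9.73) and 3.37 (0.890 to 18.9), with adjusted p of 0.312 each; these checks were chosen after seeing the data. Among planned settings, merging peaks within 1000 bp ended both calls (odds ratios 1.79 and 3.88, adjusted p = 0.678 and 0.317). Assignment within 20 kb ended the immediate-early call (odds ratio 1.83, 95% interval 0.748 to 4.91, adjusted Fisher's exact p = 0.358). For feedback genes the upper 50% by score (odds ratio 2.96, 95% interval 0.914 to 12.5, adjusted p = 0.317) and leaving out treated clone a (1.82, 1.03 to 3.35, 0.111) ended the call. Immediate-early genes had higher odds ratios in the upper 50% by score (7.64, 95% interval 2.33 to 39.6) and in the top 20000 (7.53, 1.81 to 66.8), as did feedback genes in the top 20000 (13.5, 2.11 to 564). Gained and lost refer there to the shortened lists, so such a region may still hold a weaker peak in the other treatment.

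**Figure D2:**
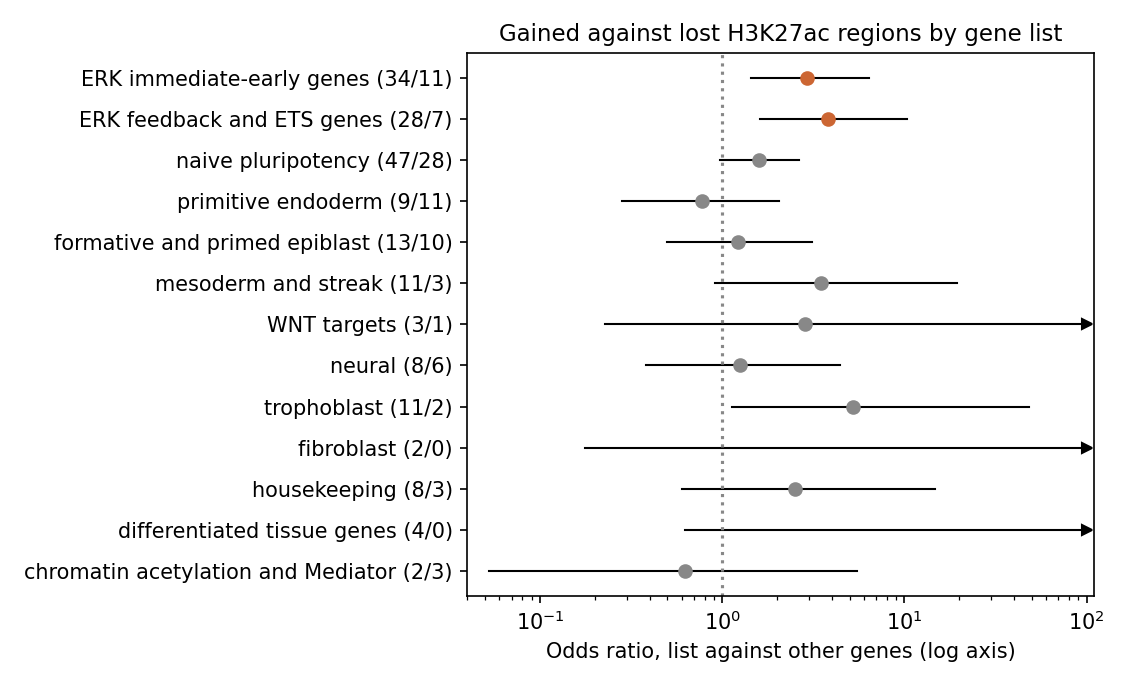
Points give the odds ratio, on a log axis, of gained against lost regions for each gene list against all other genes, with 95% intervals; arrows mark intervals that run past the axis, and numbers in brackets are gained and lost regions. Lists past adjusted p 0.05 are orange: ERK immediate-early genes (34 and 11) and ERK feedback and ETS genes (28 and 7).

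None of the other 11 lists differed from other genes in this test at an adjusted p of 0.05. Naive pluripotency genes held 47 gained and 28 lost regions (adjusted Fisher's exact p = 0.163), of which Manba, included in that list, had 16 gained. Esrrb and Jam2 held 6 gained and 0 lost, Klf5 5 and 0, Prdm14 0 and 4, Lifr 1 and 4, Socs3 0 and 3 and Tfap2c 2 and 3. Primitive endoderm genes held 9 gained, among them 3 at Cubn, and 11 lost, among them 2 each at Col4a1 and Lamb1 (adjusted Fisher's exact p = 0.737). Formative and primed epiblast genes held 13 gained, 6 of them at Grhl2, and 10 lost, 3 of them at Lefty1 and 2 at Otx2. Mesoderm and streak genes held 11 gained, with 2 each at Evx1, Cdx2 and Kdr, and 3 lost (adjusted Fisher's exact p = 0.163). Neural genes held 8 gained, with 2 each at Hes5 and Pax6, and 6 lost, 5 of them at Sox1. Trophoblast genes held 11 gained, 3 of them at Tfap2a, and 2 lost (adjusted Fisher's exact p = 0.09998). WNT targets held 3 and 1, fibroblast genes 2 (both at Twist1) and 0, housekeeping genes 8 (3 at Actb) and 3, genes of differentiated tissues 4 (all at Ptprc) and 0, and chromatin acetylation and Mediator genes 2 (both at Crebbp) and 3. Regions changed within each clone, whether or not in the other, were also combined with clone as a stratum (exact Cochran-Mantel-Haenszel test). In that test 4 lists passed: immediate-early genes (73.9% gained, adjusted p = 4.65e-10), feedback and ETS genes (72.8%, 2.79e-09), trophoblast genes (70.0%, 0.0119) and housekeeping genes (67.2%, 0.0318). A region changed in both clones enters both strata there, so the strata are not independent and the p-values overstate the evidence. Single libraries also moved these calls: naive genes passed without untreated clone a (adjusted Fisher's exact p = 0.00104) and without treated clone b (0.0187), and trophoblast genes without untreated clone b (0.0276) and without treated clone b (0.0460). With regions assigned within 20 kb, naive genes (42 gained and 12 lost, 77.8%; adjusted Fisher's exact p = 0.00401) and trophoblast genes (10 and 0; 0.0159) passed as well, and immediate-early genes (17 and 8; 0.358) did not.

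The third question was how much peak-covered length changed at whole gene loci. Around Spry4, an inhibitor of receptor tyrosine kinase signalling, it rose from 7.63 ± 3.46 kb in untreated to 31.4 ± 0.125 kb in treated cells (SD, n = 2 clones; log2 change 2.04 ± 0.29 SE, limma adjusted p = 0.0300). It also rose around Etv4 (2.86 ± 1.07 to 14.3 ± 2.19 kb), Phlda1 (4.00 ± 0.0325 to 14.3 ± 1.95 kb), Egr3 (1.72 ± 1.01 to 9.18 ± 1.03 kb) and Dusp5 (4.08 ± 0.0926 to 10.6 ± 0.0226 kb). It fell around Lefty1 (30.6 ± 3.65 to 13.8 ± 1.63 kb) and Socs3 (25.8 ± 0.332 to 14.7 ± 1.67 kb). Over 16049 loci, 642 rose and 461 fell, 1103 in all, which had 1016 distinct sets of covered lengths because neighbours share windows; the median change of all loci was 0.08 on the log2 scale. With clone as a factor 6125 loci passed, 3639 longer and 2486 shorter, including all 1103. With a library left out, which leaves a single library in that group, it was 0 without treated clone a, 5 without untreated clone a, 103 without treated clone b (30 longer and 73 shorter, so the balance turned) and 568 without untreated clone b. Loci at unadjusted p under 0.05 numbered 4464 with all libraries and 3225, 3272, 3136 and 3526 in those fits, and the median size of change of the loci called with all libraries, where still fitted, was 1.09, 1.03, 1.05 and 1.10 on the log2 scale, against 1.08. Those loci were picked with the same libraries, so their sizes are no separate test. Spry4 changed by 2.04 without treated clone a (adjusted p = 0.0861). Regrouped by clone, limma called 0 loci (970 at unadjusted p under 0.05), and in the crossed grouping 0 (1). These regroupings put the difference between treatments into the residual spread, which lowers their power. Their lack of calls is therefore no control for the 1103.

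**Figure D3:**
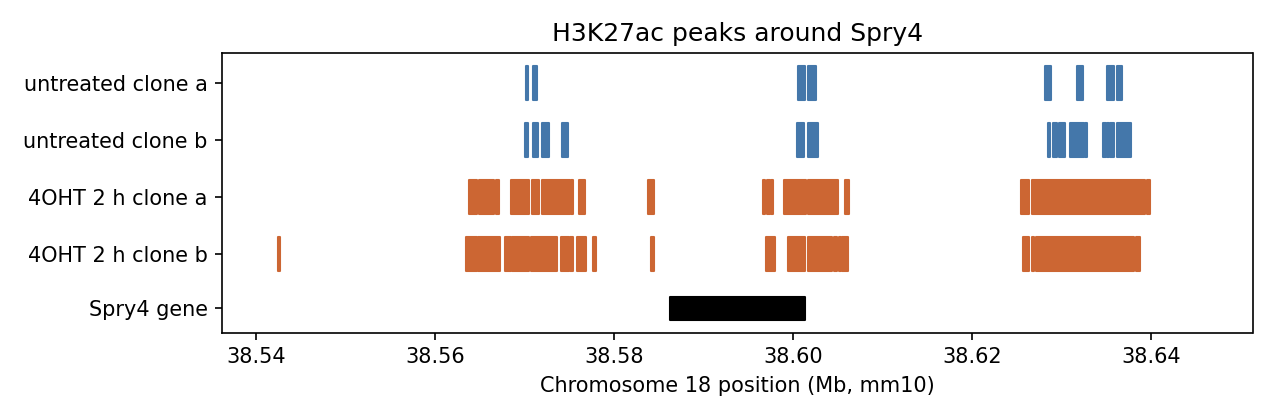
Bars mark H3K27ac peaks in each library across the Spry4 gene and 50 kb on either side (chromosome 18, position in Mb). Peaks cover 5.18 and 10.1 kb in untreated clones a and b and 31.3 and 31.5 kb in the treated ones.

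Among immediate-early genes, 5 of 31 loci rose and 0 fell: Egr2 (log2 change 0.90), Phlda1 (1.72), Egr3 (2.20), Arc (0.66) and Fosl2 (1.67). Adjusted over the list alone, 10 rose and 1 fell. Among feedback and ETS genes, 6 of 21 rose and 0 fell: Etv4 (2.17), Spry2 (0.60), Spry4 (2.04), Dusp5 (1.28), Spred1 (1.56) and Dusp4 (1.24). Adjusted over the list alone, 8 rose. The median log2 change was 0.27 in the immediate-early list and 0.38 in the feedback list, against 0.26 in the chromatin list, 0.22 in the housekeeping list and 0.45 in the fibroblast list. Both ERK lists stood above other loci in camera with the preset correlation (adjusted p = 0.0306 each). With an estimated correlation camera gave adjusted p of 0.777 each. That version rests on the few residual degrees of freedom of 4 libraries, so it could hardly pass any list and decides nothing here. For primitive endoderm genes the unadjusted camera p rose from 0.0627 to 0.179 in it, although their estimated correlation was -0.0107. Fry, which asks whether the members moved one way, gave adjusted p of 0.0573 and 0.0684. With clone as a factor camera gave adjusted p of 0.0385 and 0.0645 (0.802 each with an estimated correlation), fry gave 0.00275 and 0.0942, and 17 rose and 2 fell among immediate-early genes and 12 rose and 2 fell among feedback genes.

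Loci of genes always reported varied in size of change. Egr1, a first-wave ERK target, had 6.10 ± 0.675 kb untreated and 7.04 ± 1.01 kb treated (adjusted p = 0.496), Fos 11.5 ± 2.63 and 11.2 ± 4.51 kb (adjusted p = 0.905), and Dusp6, an ERK phosphatase, 9.36 ± 0.0799 and 9.06 ± 1.42 kb (adjusted p = 0.850). Nanog, a pluripotency factor, had 35.6 ± 4.54 and 30.3 ± 3.11 kb (adjusted p = 0.336; 0.00352 with clone as a factor), and Klf4 13.1 ± 0.672 and 11.5 ± 1.27 kb (adjusted p = 0.397). Esrrb had 45.1 ± 2.52 and 51.1 ± 3.03 kb (0.306; 0.00236 with clone) and Pou5f1 26.5 ± 0.201 and 32.1 ± 2.33 kb (0.172; 0.00546 with clone). Actb had 8.16 ± 1.05 and 12.9 ± 1.55 kb (0.0732; 0.00134 with clone). Gata6, a primitive endoderm factor, had 0.106 and 0.304 kb and was below the filter, and Fgf5 had 0 kb in all libraries.

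**Figure D4:**
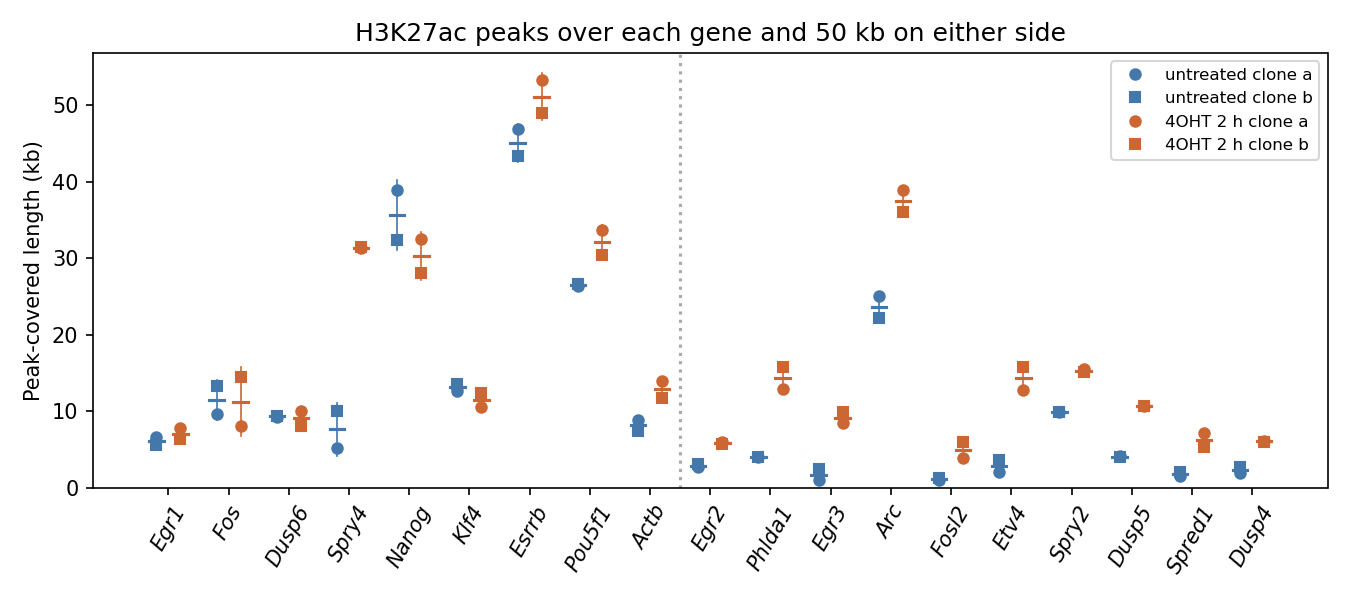
Points give peak-covered length in kb per library over each gene and 50 kb on either side; lines and bars are the mean and SD of the clones. The genes left of the dotted line are always reported and those to its right are the other ERK list members past the threshold; Spry4 goes from 7.63 to 31.4 kb.

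Naive, formative, mesoderm and neural lists had members that rose and members that fell. In the naive list Manba rose (1.48) and Socs3 fell (-0.79). In the formative and primed list Cldn6 (1.34), Cdh2 (1.22) and Pou3f1 (1.56) rose, and Lefty1 (-1.12), Lefty2 (-1.09) and Dkk1 (-1.80) fell. Lefty1 and Lefty2 are neighbours with overlapping windows and are not separate results. In the mesoderm list Cdx2 (2.57), Evx1 (2.33), Mesp1 (1.68) and Fgf8 (0.72) rose, and Wnt3 (-1.51), Msgn1 (-1.10) and Gsc (-0.85) fell. In the primitive endoderm list Col4a1 (-1.60) and Lamb1 (-0.94) fell. In the neural list Nes (0.92) rose, and Neurod1 (-2.24) and Sox1 (-0.73) fell. Plac1 of the trophoblast list rose by 1.40, and Cdx2 is also in it. S100a4 of the fibroblast list (3.18), Ptprc of the differentiated tissue list (2.48) and Smarca4 of the chromatin list (0.77) rose. In the WNT and housekeeping lists 0 members passed, while with clone as a factor 1 of 9 WNT targets rose and 0 fell, and 7 of 18 housekeeping genes rose and 1 fell. Adjusted over the list alone, 3 rose and 2 fell in the naive list, 5 and 4 in the formative list, 4 and 3 in the mesoderm list, 1 and 2 in the primitive endoderm list, 3 and 2 in the neural list, 3 and 1 each in the trophoblast and fibroblast lists, 2 and 0 in the differentiated tissue list and 1 and 0 in the chromatin list. None of these lists passed camera (lowest adjusted p = 0.204) or fry's test of one direction (lowest adjusted p = 0.0573). In fry's test of change in either direction, which does not compare a list with other loci, every list but the WNT targets (adjusted p = 0.238) passed, among them the immediate-early and formative lists (0.00125 each), the naive and housekeeping lists (0.00298 each) and the chromatin list (0.0276). With clone as a factor, fry's test of one direction called the differentiated tissue list (adjusted p = 0.00275, 3 rose and 1 fell) and the chromatin list (0.0446, 9 rose and 1 fell). Camera called none of them. In fry's test of either direction with clone, trophoblast genes (adjusted p = 0.0575) and WNT targets (0.151) did not pass. The median and mean log2 change differed in sign in the naive list (-0.05 and 0.01) and the formative list (-0.06 and 0.03), and in the neural list a median of 0.75 stood beside a fry test pointing down.

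The largest increases were at Ap1s3 (0.105 ± 0.148 to 8.85 ± 1.66 kb; log2 change 3.96), S100a2 (3.22), Gsn (3.22), and S100a4 and S100a5 (3.18 each); the S100a genes share windows and are not separate results. Among the largest decreases were those at AI593442 (4.79 ± 0.175 to 0.159 ± 0.224 kb; log2 change -3.05), Slc16a7 (-2.93), Defb5 (-2.89) and Defb6 (-2.82), the last pair with overlapping windows. The untreated levels of Ap1s3 and Gsn and the treated levels of AI593442 and Slc16a7 lie at or near 0, so their changes depend on the pseudocount. Without treated clone a the changes were 4.14 at Ap1s3, 3.67 at Gsn, 3.29 at S100a4 and -2.93 at Slc16a7 (adjusted p = 0.0583, 0.0615, 0.0583 and 0.0589).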

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

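Of 501 alternative values for 45 results, 378 were taken as unchanged and 31 reversed. The main results, such as region and locus counts and the ERK lists, were less stable. Of their values 59 were unchanged, 41 moved and 9 lost their call. Of the other values 319 were unchanged, 31 reversed, 30 lost a call and 12 gained one. Each reversal was of a result that did not pass its main test. A tested value was unchanged if it kept its direction and its side of the threshold. Counts were unchanged within a set ratio of the main value. The share of regions changing alike in the clones was allowed 5 percentage points, and Jaccard indices the SD between pairs. Counting each gene once and leaving out a list's gene with the most changed regions were settings chosen after seeing the data; the others were planned. Read depth is unknown, which limits any statement about a missing peak. Why a value moved between these settings was not tested. A left-out library leaves the other one of its treatment to decide alone, and that one is then assumed to vary like the other group.

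Gained and lost regions numbered 2581 and 2517 in the upper 50% by score, 1859 and 1641 in the top 20000, 2569 and 2508 after merging within 1000 bp, and 7101 to 13200 and 7171 to 12515 with a library left out. In the upper 50% and the top 20000, gained and lost refer to the shortened lists. Regions that changed in the same direction made up 100% with the top 20000 absent from the other list. Loci past the threshold numbered 6125 (3639 longer, 2486 shorter) with clone as a factor (the replicate block), 671 (393, 278) with 10 kb windows, 141 (88, 53) with no filter, and 0 to 568 (0 to 406, 0 to 162) with a library left out; without treated clone b, 30 were longer and 73 shorter. The block also called Nanog, Esrrb, Pou5f1 and Actb and ended the camera call of feedback and ETS genes. It gave fry calls of one direction to immediate-early, differentiated tissue and chromatin genes, and ended fry's call of either direction for trophoblast genes. It changed no other call among the genes always reported or the 10 loci with the largest changes.

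Lists past adjusted p 0.05, 2 in the main test, numbered 1 in the upper 50% by score, 0 after merging, 0 with each gene counted once, 0 without the gene with the most changed regions, 3 with assignment within 20 kb (naive, trophoblast and feedback genes), 4 with the block (which also counts regions changed within a single clone, so the rise cannot be put down to the block alone) and 1 to 4 with a library left out. In the block test a region changed in both clones counts in the stratum of each, so the strata are not independent. The share of gained regions at immediate-early genes lost its call at 66.7% after merging, 68% within 20 kb, 75% with each gene counted once and 69.4% without Phlda1. That of feedback and ETS genes lost it at 76.5% in the upper 50% by score, 81.2% after merging, 78.6% with each gene counted once and 75.9% without Spry4. With a library left out this share ran from 61.5% to 85.7%, but the share at other genes moved too. It was 61.5% against 39.2% at other genes without untreated clone b, and 85.7% against 60.3% without treated clone b. Without treated clone a it was 75.7% against 63.2%.

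Shares on the other side of that at other genes were as follows. In the upper 50% by score the share was 40% for naive and WNT genes and 50% for neural genes. In the top 20000 it was 40.9% for naive, 53.8% for formative, 33.3% for mesoderm, 50% for WNT, 0% for neural and 100% for chromatin genes. With each gene counted once it was 47.1% for naive and 50% for formative genes, which had 41.2% without Grhl2 and 46.2% with the block. It was 56.2% for primitive endoderm genes within 20 kb, 50% for neural genes with equal lengths, and 57.1% for chromatin genes with 50% of a region covered.

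With a library left out, shares ran from 42.9% to 72.8% for naive, 29.3% to 60% for primitive endoderm, 40.5% to 56.8% for formative, 27.3% to 85.7% for WNT, 44.4% to 66.7% for neural, 40% to 100% for fibroblast and 20% to 82.4% for chromatin genes. The share at other genes also moved with the library left out. For naive genes, 42.9% without untreated clone b stood above the 39.3% at other genes. Their 55.7% without treated clone a stood below 63.3%. A list's range therefore does not show on which side of other genes it lay. The log2 change of Egr1 was -0.041 with 100 kb windows. That of Dusp6 was 0.015 with 10 kb windows, 0.18 with 100 kb windows, 0.020 with equal lengths and -0.20 to 0.10 with a library left out, and that of Fos -0.47 to 0.33.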

Other observations

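The tests of merging within 5 kb, of the HOX list and of each HOX cluster were chosen only after their results had been seen, as was that of pairs under 5 kb, and the test of counting each gene once was added after the data had been seen. HOX genes, which pattern the body axis, were examined as an extra list. Of 35 HOX loci in the fit, 18 rose and 1 fell, and their median log2 change of 1.16 was at the 100th percentile of 10000 random lists matched on covered length, and also of random runs of neighbouring genes, a comparison added because cluster members share windows. The clusters went apart. Clusters a and d had median changes of 1.20 (9 of 11 loci rose) and 2.43 (9 of 9 rose), above the central 95% of runs of their size (up to 0.61 and 0.68). Cluster b had -0.090 (0 of 6 passed), within its range, and cluster c -0.67 (1 of 9 fell), below its range of -0.56 to 0.68. A rise of HOX genes as a class is thus a description of clusters a and d alone, whose members share most of their windows and are not separate results.

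As a hypothesis, loci of actin cytoskeleton genes and targets of the transcription factor SRF may have gained covered length. Their median log2 change over 25 loci was 0.35, at percentile 99.95 of random lists matched on covered length (central 95% from -0.09 to 0.23). Only 2 of the 25 passed the main test, and 12 rose and 4 fell with clone as a factor.

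Gained regions lay nearer gene ends than lost ones, and 3 technical explanations were set against this. With lists of equal length the odds ratio was 3.02 (95% interval 2.62 to 3.49), which argues against list length. Over all regions changed within clone b, the clone with the lower value, it was 1.67 (1.55 to 1.80), against 2.69 in clone a. These sets include the regions changed in both clones that define the pattern. The result is thus partly given in advance and is no separate test of a single clone as the source. Without changed regions within 2 kb of a region called in all 4 libraries the odds ratio was 3.45 (2.89 to 4.13), which argues against shoulders of constant peaks. Differences in read depth or in the strength of immunoprecipitation between treatments stay open, as does a response to ERK, which these 4 libraries do not separate from them.

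Changed regions that lay close together shared their direction: 97.7% of neighbours under 5 kb apart, 78.1% at 5 to 20 kb, 65.4% at 20 to 50 kb, 60.4% at 50 to 100 kb and 54.3% at 100 to 500 kb, against 50.4% to 50.5% on average in 1000 permutations within chromosomes. After merging peaks within 5 kb the share at 5 to 50 kb was 74.6% (95% interval 70.1 to 78.7; highest permuted 59.1), which argues against domains split at gaps under 5 kb as the whole source at that distance. Merging leaves no pair under 5 kb, so for the 97.7% there the splitting of single domains stays open. Regions that separate the clones gave 70.4% (67.4 to 73.3) at 5 to 50 kb, against 71.0% (69.1 to 72.9) for treatment. Local differences that also arise between the clones could therefore account for the clustering at 5 to 50 kb, which says nothing specific about ERK. Regions that separate the clones were called in both libraries of a clone. They do not isolate differences in coverage or calling from other differences between the clones. The clone comparison was not made at other distances.

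The excess of gained regions at ERK genes was set against 3 explanations. With each gene counted once, the odds ratio was 2.76 for immediate-early genes (0.953 to 9.73; Fisher's exact p = 0.0447) and 3.37 for feedback and ETS genes (0.890 to 18.9; p = 0.0602), against 2.93 and 3.79 over regions. Both intervals include 1 and the value over regions, and the genes (15 net gained and 5 net lost, and 11 and 3) are too few to decide whether a few genes carry the excess. The bound written down beforehand was a p of 0.05, by which a few genes would be excluded for immediate-early genes and would account for the excess at feedback genes; both readings were withdrawn after the values were seen, since the intervals do not bear them out. Away from gene ends the odds ratios were 2.61 (1.25 to 5.85) and 3.50 (1.45 to 9.66), which argues against gains at gene ends in general. In the split by clone Fisher's exact p was 0.792 and 0.195, with intervals that overlap those of the treatment, so unstable calls at these genes stay open.

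The genes with the most one-sided changes, chosen after their values were seen, were Manba (16 gained, 0 lost), Tmem178b (11 and 0), Tmem132d (11 and 1), Bcl2l14 (10 and 0) and Pard3b (9 and 0), and on the lost side Magi1 (0 and 12) and Clybl (0 and 10).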
